A study of Caenorhabditis elegans with 3 samples.

How the data were processed

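ChIP-seq of a tagged EGL-27 was done by the submitters in whole L2 larvae of mixed sex, with chromatin sheared by sonication, in 3 biological replicates per the labels. All form 1 group. Tests within the peak set take peaks, genes or sequence windows as units, so their p-values do not measure the spread between animals or cultures.

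Per the file headers and notes deposited with each library, the authors made lists of peaks and background from each replicate's alignments with a control, a pooled list from the 3 replicates with a control, and a set kept at an optimal IDR threshold from the pooled and replicate lists, each on ce10 and ce11. The aligner, the caller and the IDR threshold are not given in the sources used here, and the control was not used here. Each region has a signal value that the authors deposited, with no scale named, a −log10 q-value that the authors deposited, which reaches a highest value shared by many regions, and the offset of its summit. The IDR set was checked against the pooled list: on ce11 it held 1997 regions, all present in the pooled list, and 1997 pooled regions had a signal at or above its lowest. All had the highest q-value, as had 2210 pooled regions. In 3 cases a second peak shared an interval. The IDR set on ce10 held 2074 regions. No list held regions on mitochondrial DNA. No region was identical in summit and signal between any pair of replicates. The files hold no read counts, so depth is unknown and no counting interval is given.

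Positions are on ce11, with every region inside the chromosome lengths of the reference genome (WBcel235), and genes from Ensembl release 115. Lists on ce10 were used for peak counts, shared peaks, rank agreement and the X ratio. Every summit was placed in 1 class, in this order: promoter (1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene), coding exon, UTR, intron, noncoding RNA gene and other intergenic. Shares were compared with 100000 binomial draws of as many random positions per chromosome, two-sided, with Benjamini-Hochberg adjustment over 6 classes. The smallest p these draws can give is 1e-05. A promoter summit was assigned to the nearest 5' end. Lists were matched by symbol, and 205 of 19973 genes have a symbol used by more than 1 gene, each counted as a gene. Each of 34 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05.

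Replicate values (mean ± SD, n = 3) come from the 1997 strongest regions of each replicate's list, as many as there are IDR peaks. An IDR peak counted as found in a replicate when at least 1 bp overlapped one of these. Random placement kept chromosome and median width (1000 placements). Rank agreement was Spearman's rho of the signals across IDR peaks with 100000 permutations. The density on X was compared with autosomes by an exact binomial test on length.

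For sequence, windows of 100 bp on each side of the summit were compared with windows centred 500 bp to each side of it. The planned sign test of a summit against the mean of its flanks was biased on simulated data and was replaced by an exact test that takes the summit as equally likely to be any of the 3 windows. It covered 16 consensus sites and, as a search, all 2080 hexamers with both strands together, each with Benjamini-Hochberg adjustment. Random windows over 1 kb from pooled summits, matched on G+C content, served as another control (Fisher's exact test, adjusted over 16 sites). Summits within 100 bp of noncoding RNA genes of 6 types were compared with binomial draws as above, and the MEX sequence with at most 2 mismatches was compared between X and autosomes by Fisher's exact test.

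The genes named are the 10 strongest promoter peaks found in every replicate, the 3 strongest bound members of each list with more bound genes, the strongest bound member of every other list, 12 genes fixed beforehand, and the 5 hexamers of largest ratio. This rule, the gene lists and the tests of the comparisons, except the replaced sign test, were fixed before the data were examined. Regions outside promoters and mep-1 were named after their values were seen.

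The alternatives were the other build, the stronger 998 peaks (the files hold no IDR value per peak, so a stricter IDR was replaced by signal), other overlap rules, peaks found in every replicate, each replicate left out in turn (keeping the IDR peaks found in both others, IDR was not recomputed here, so the number of peaks falls as well), 500 and 2000 bp promoters, every gene in the window, the weaker 50% of the pooled list or the number of genes as background, a logistic model with the distance to the next gene, windows of 50 bp, promoters of unbound genes, and permuted consensus letters (at most 20). Promoters of unbound genes were compared with the promoter summits only. Chosen after seeing the data were the 5' ends of all transcripts, the windows matched on G+C as a control for the sites and leaving out the block around egl-27. Self-tests on simulated data called 0 of 120 position classes, 2 of 600 lists and 0 of 16 sites in unchanged data, and called 75% of planted lists of 20 genes with 30% bound. A planted promoter excess of 24.0 percentage points was estimated as 25.5. Overlap calls were checked against bedtools 2.31.1, with 0 of 11982 differing. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.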

Results

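Binding of EGL-27 to the genome of Caenorhabditis elegans was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole larvae of the L2 stage. EGL-27 is a homologue of the metastasis-associated MTA subunits of the NuRD chromatin remodelling complex and carries a GATA-type zinc finger. The animals, of strain OP177, expressed EGL-27 with a GFP and FLAG tag at its C-terminus. There was 1 group with 3 biological replicates, so the comparisons that follow set bound against unbound sequence, genes and chromosomes, and the replicates against each other. The authors' peak set, kept by the irreproducible discovery rate (IDR), held 1997 regions on ce11, with a median width of 350 bp and a median signal of 50.8 (range 34.8 to 378). The longer list of peaks and background from the pooled replicates held 30000 regions. The replicates' own lists held 13245, 30000 and 30000 regions for replicates 1, 2 and 3. The number of reads behind each list is unknown from the files, and the signal is the authors' value for each region, used here to rank and compare regions within a list.

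The strongest binding lay in introns, in intergenic sequence and in promoters, among them those of 3 ribosomal protein genes. The region of highest signal (378) was in an intron of Y111B2A.12, at chromosome III, 12612476 to 12612844. Next came a pair of regions in introns of pqn-41, at III, 1925017 to 1925542 (signal 308) and III, 1921104 to 1921641 (signal 299), and a region between genes at X, 11093938 to 11094380 (signal 286). Among promoters, the strongest region stood upstream of rpl-3, a protein of the large ribosomal subunit (III, 3867444 to 3867705, signal 278, summit at -280 bp from the 5' end). It was followed by cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins (II, 10563452 to 10563703, signal 268, summit at -166 bp), and Y17G9B.5 (IV, 4749961 to 4750202, signal 266). The promoters of rpl-15 (signal 254), puf-9, which encodes a Pumilio-family RNA-binding protein (signal 238), rpl-35 (signal 223), ska-3 (signal 219), H41C03.3 (signal 205), tag-340 (signal 199.9) and nspc-17 (signal 199.8) completed the strongest 10. These 10 were chosen among promoter regions found in every replicate. Among the 1192 IDR peaks listed in all 3 replicates, the puf-9 region had a mean rank of 21.7 ± 4.93 (SD, n = 3) and the rpl-3 region one of 45.3 ± 69.0 (SD, n = 3).

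The replicates shared a part of their strongest regions, and replicate 1 shared the least. Of the 1997 strongest regions of replicate 2, 1281 (64.1%) overlapped those of replicate 3, while of those of replicate 1, 586 (29.3%) overlapped those of replicate 2 and 557 (27.9%) those of replicate 3. Of the 1997 IDR peaks, 499 (24.99%) overlapped the 1997 strongest regions of every replicate. Random placement gave a mean of 0.003 and at most 1 in 1000 placements. The IDR peaks were themselves derived from these replicates, so an overlap above random placement was built in and is no independent measure of reproducibility. Replicate 1 covered 640 of the IDR peaks in this way, replicate 2 covered 1552 and replicate 3 covered 1582. In the whole lists the numbers were 1200, 1987 and 1990. The signals of IDR peaks were correlated across peaks between replicates 2 and 3 (Spearman's rho 0.511 over 1980 peaks), replicates 1 and 2 (rho 0.419 over 1195 peaks) and replicates 1 and 3 (rho 0.371 over 1197 peaks). Each of these 3 correlations had a permutation p of 1e-05, two-sided, the smallest that the permutations can give, and peaks are not independent replicates. Without replicate 1, 1246 IDR peaks were found in both remaining replicates, without replicate 2 there were 544 and without replicate 3 there were 565. Values other than rho given below without a replicate come from these smaller sets of peaks, of which those without replicate 2 or 3 require overlap with replicate 1.

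**Figure D1:**
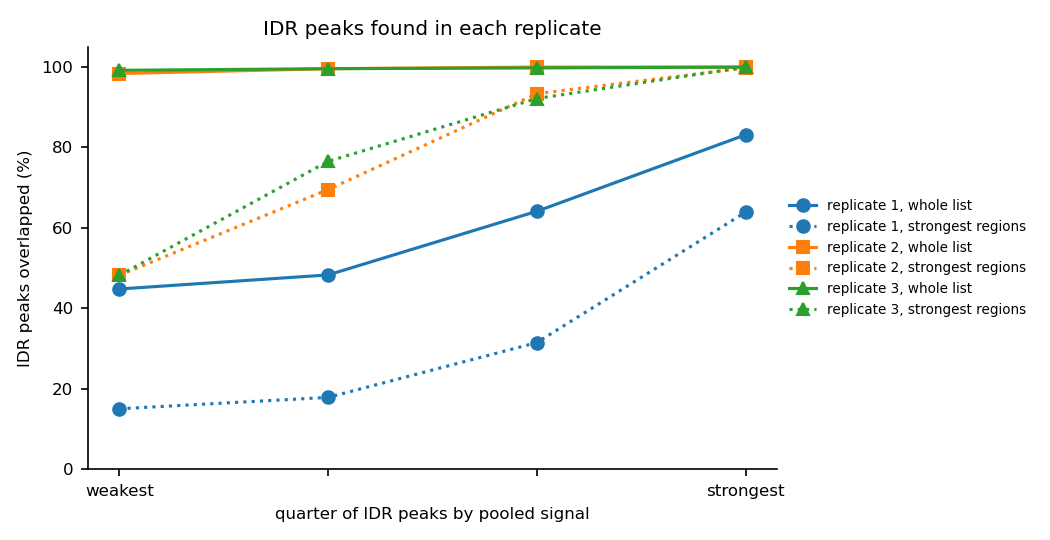
Share of IDR peaks (y axis, %) overlapped by each replicate's whole list (solid lines) or by its 1997 strongest regions (dotted lines), for 4 bins of pooled signal from weakest to strongest (x axis). The whole list of replicate 1 held 44.8% of the weakest bin and 83.2% of the strongest, while the other replicates held 98.4% or more of every bin.

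EGL-27 summits were concentrated in promoters and nearly absent from coding exons. A summit lay within 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene for 930 of 1997 IDR peaks (46.6%), against 21.1% of random positions. Only 13 summits (0.651%) fell in coding exons, against 19.9% of random positions, and with the peaks shared by both others the share was 0.401% without replicate 1, 0.184% without replicate 2 and 0.354% without replicate 3. Introns held 22.7% of summits and 30.7% of random positions, UTRs 1.60% and 3.10%, and genes of noncoding RNAs 3.61% and 0.803%. These 5 classes differed from the random positions (100000 binomial draws, two-sided, adjusted p between 1.5e-05 and 2.52e-04), and other intergenic sequence did not (24.9% and 24.4%, binomial draws, adjusted p = 0.619). The UTR call was lost among peaks found in every replicate (binomial draws, adjusted p = 0.528) and among those shared by both others without replicate 2 (adjusted p = 0.539) or replicate 3 (adjusted p = 0.280). In the replicates' own strongest regions the promoter share was 40.8% ± 7.81 (SD, n = 3) and the coding exon share 4.54% ± 6.30 (SD, n = 3), the latter being 11.8% in replicate 1 and 0.951% and 0.851% in replicates 2 and 3.

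**Figure D2:**
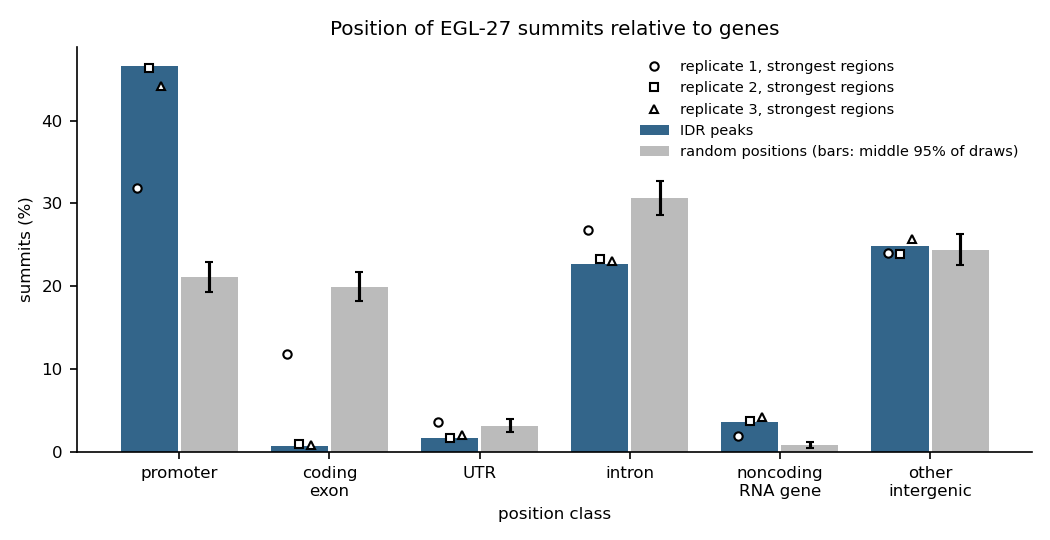
Percent of summits (y axis) in each position class (x axis) for IDR peaks (blue bars), random positions (grey bars, with the middle 95% of draws) and each replicate's strongest regions (points). Promoters held 46.6% of IDR summits against 21.1% at random, and coding exons 0.651% against 19.9%.

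The X chromosome carried more EGL-27 peaks per megabase than the autosomes. There were 447 peaks on X (25.23 per Mb) and 1550 on the autosomes (18.8 per Mb), a ratio of 1.34 (exact binomial test, two-sided, p = 8.87e-08). The replicates' strongest regions gave a ratio of 1.35 ± 0.0349 (SD, n = 3). A smaller part of the X peaks lay in promoters, 39.4% against 48.6% on autosomes (Fisher's exact test, two-sided, p = 5.67e-04), while promoters made up 17.6% of X and 22.3% of autosomal sequence. Among autosomes the density ran from 15.3 per Mb on V to 23.8 per Mb on III. The binomial test took the autosomes together, so its p-value does not measure this spread between chromosomes.

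Ribosomal protein genes were the gene group with the largest number of bound promoters. By share, the smaller groups of NuRD and MEC genes (40%) and heterochronic genes (33.3%) were higher. In all, 912 of 19973 protein-coding genes (4.57%) had a summit assigned to their 5' end, with a median summit position of -218 bp from it. With only the peaks shared by both others, the bound genes numbered 576 without replicate 1, 254 without replicate 2 and 264 without replicate 3. Of 80 ribosomal protein genes 25 were bound (31.3%, against 4.46% of other genes, Fisher's exact test, two-sided, adjusted p = 1.26e-13). These were 16 of 49 genes of the large subunit and 9 of 31 of the small subunit, led by rpl-3, rpl-15 and rpl-35. Per replicate, 25.4% ± 11.2 (SD, n = 3) of the group was bound. When every gene in the window of a summit was counted, and not only the nearest, the excess over other genes rose from 26.8 to 49.2 percentage points. It was 7.61 points among peaks found in every replicate and, among those shared by both others, 25.97 without replicate 1, 7.51 without replicate 2 and 7.46 without replicate 3 (Fisher's exact test, adjusted p of 0.00121 or less in each). The shares of the group bound in these sets were 8.75%, 28.75%, 8.75% and 8.75%. Other genes were bound less often in them too, so a smaller number of points is not by itself a weaker excess.

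Genes of mitochondrial respiration and of protein folding were also bound more often than other genes. Of 40 genes of the respiratory chain 9 were bound (22.5%, Fisher's exact test, adjusted p = 7.16e-04). Examples were cox-5A (signal 175, summit at -286 bp) and cox-5B (signal 128, summit at -55 bp), subunits of cytochrome c oxidase, and atp-1, the alpha subunit of ATP synthase (signal 111). Of 25 genes of the heat shock and unfolded protein responses 5 were bound (20%, Fisher's exact test, adjusted p = 0.0276). They included hsp-1, an Hsp70 chaperone (signal 144, summit at -396 bp), hsp-3, a chaperone of the endoplasmic reticulum (signal 98.8, summit at -49 bp), and xbp-1, a transcription factor of the unfolded protein response (signal 96.6, summit at -18 bp). With every gene in the window the excess of this group over other genes rose from 15.5 to 29.99 percentage points. Among peaks found in every replicate the respiratory chain no longer passed Fisher's exact test (adjusted p = 0.518), and it did not pass among the peaks shared by both others without replicate 2 (adjusted p = 0.511) or replicate 3 (adjusted p = 0.134).

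Promoters of NuRD and MEC complex genes and of genes of developmental timing were bound in the IDR set, and these calls rested on few genes. Of 10 NuRD and MEC genes 4 were bound (40%, Fisher's exact test, adjusted p = 0.00618). These were lin-53, the RbAp46/48 homologue (I, 9619809 to 9620158, signal 74.1), dcp-66 (I, 7542132 to 7542481, signal 55.3), lin-40, the other MTA homologue of the worm (V, 3703923 to 3704272, signal 47.4, summit at -890 bp), and mep-1 (signal 34.8), which was named after its value was seen. Of 9 heterochronic genes 3 were bound (33.3%, Fisher's exact test, adjusted p = 0.0315): lin-14, a transcription factor of early larval fates (X, 11465233 to 11465582, signal 63.8), lin-66 (IV, 13887642 to 13887739, signal 60.5) and lin-28, an RNA-binding protein (I, 8411216 to 8411565, signal 42.9). In all, lin-14 had 6 IDR peaks in its gene body and 1000 bp upstream. Among peaks found in every replicate neither group passed Fisher's exact test (adjusted p = 0.518 for both). In that set 1 gene of each group was bound (10% and 11.1%), 8.83 and 9.94 percentage points above other genes, of which fewer were bound as well. By the same exact test on the peaks shared by both others, the NuRD and MEC call held without replicate 1 (adjusted p = 0.0209) and was lost without replicate 2 (adjusted p = 0.511) or replicate 3 (adjusted p = 0.422), and the heterochronic call was lost without replicate 1 (adjusted p = 0.107), replicate 2 (adjusted p = 0.511) or replicate 3 (adjusted p = 0.422). On the 998 peaks of highest signal 20% of NuRD and MEC genes and 22.2% of heterochronic genes were bound, and both calls were lost in the exact test (adjusted p = 0.103), and the heterochronic call with promoters of 500 bp (adjusted p = 0.147).

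Large families of environmental and sensory genes were bound less often than other genes. Of 1309 chemoreceptor genes 6 were bound (0.458%, Fisher's exact test, adjusted p = 3.21e-18), the strongest being srz-62 (signal 112.2). F-box genes (4 of 322, strongest fbxb-85, signal 134, Fisher's exact test, adjusted p = 0.0116) and C-type lectins (3 of 240, strongest clec-126, signal 50.04, Fisher's exact test, adjusted p = 0.0325) were low as well. The difference of chemoreceptors from other genes was -4.40 percentage points, and -2.76, -1.20 and -1.25 with the peaks shared by both others without replicates 1, 2 and 3, each passing the test. On the peaks shared by both others without replicates 1, 2 and 3, the exact test gave an adjusted p of 0.107, 0.679 and 0.422 for F-box genes and of 0.0833, 0.511 and 0.397 for C-type lectins. The shares bound there stayed below those of other genes. They were 0.932%, 0.311% and 0.311% for F-box genes (differences of -1.98, -0.977 and -1.03 points). For C-type lectins they were 0.417%, 0% and 0% (-2.50, -1.29 and -1.34 points). The F-box call was also lost in the exact test on the 998 peaks of highest signal (adjusted p = 0.103), and that for C-type lectins with promoters of 500 bp (adjusted p = 0.146).

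The other 26 of 34 lists did not pass the test, and 12 of the 34 had a p under 0.05 by Fisher's exact test before adjustment. The proteasome (5 of 33 bound, strongest rpn-3, signal 106) had an adjusted p of 0.0608, neuropeptides (1 of 140, ins-39, signal 160.0) one of 0.0774, cell cycle genes (4 of 27, strongest pcn-1, the PCNA homologue, signal 104.6) one of 0.0959 and Hedgehog-related genes (0 of 84) one of 0.0959, all by Fisher's exact test. By the same exact test the proteasome passed with promoters of 500 bp (adjusted p = 0.0367) or 2000 bp (adjusted p = 0.0423), neuropeptides with 500 bp (adjusted p = 0.0484), with the 5' ends of all transcripts (adjusted p = 0.0405) or with every gene in the window (adjusted p = 0.0151), and cell cycle genes without replicate 1 (adjusted p = 0.0402). Hedgehog-related genes passed that exact test with 2000 bp (adjusted p = 0.0474) or with every gene in the window (adjusted p = 0.0368), and genes of EGF, FGF and Ras signalling with 2000 bp (adjusted p = 0.0474). The proteasome, neuropeptides and Hedgehog-related genes also passed in a logistic model with the distance to the next gene. Signalling lists had shares of 6.25% to 18.2%, none past the test: Wnt 2 of 32 (strongest mig-5, a Dishevelled homologue, signal 111), Notch 2 of 11 (osm-11, signal 40.5), TGF-beta 2 of 16 (sma-2, signal 37.9), EGF, FGF and Ras 2 of 18 (gap-1, signal 37.0) and insulin and longevity 2 of 21 (daf-16, signal 58.2). Among regulators, 17 of 269 nuclear hormone receptors (nhr-1, signal 102), 3 of 63 ceh homeobox genes (ceh-38, signal 135), 1 of 10 Hox genes and cofactors (ceh-20, a PBX homologue, signal 50.9), 1 of 44 bHLH and T-box genes (hlh-11, signal 76.7) and 0 of 11 GATA factors were bound. Tissue lists gave 3 of 36 for neurons (egl-21, signal 47.7), 2 of 25 for epidermis and seam (tlp-1, signal 57.7), 2 of 25 for body-wall muscle (unc-60, signal 43.0) and 1 of 28 for intestine (pept-1, signal 48.6). No gene of the pharynx (17), glia and coelomocyte (11), germline (34) or major sperm protein (31) lists was bound. Collagens (8 of 175, col-160, signal 65.6), histones (3 of 72, his-37, signal 156), cytochrome P450 and UGT genes (3 of 141, cyp-13A2, signal 87.7) and oxidative stress genes (1 of 22, wdr-23, signal 81.9) had adjusted p of 0.426 or more.

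**Figure D3:**
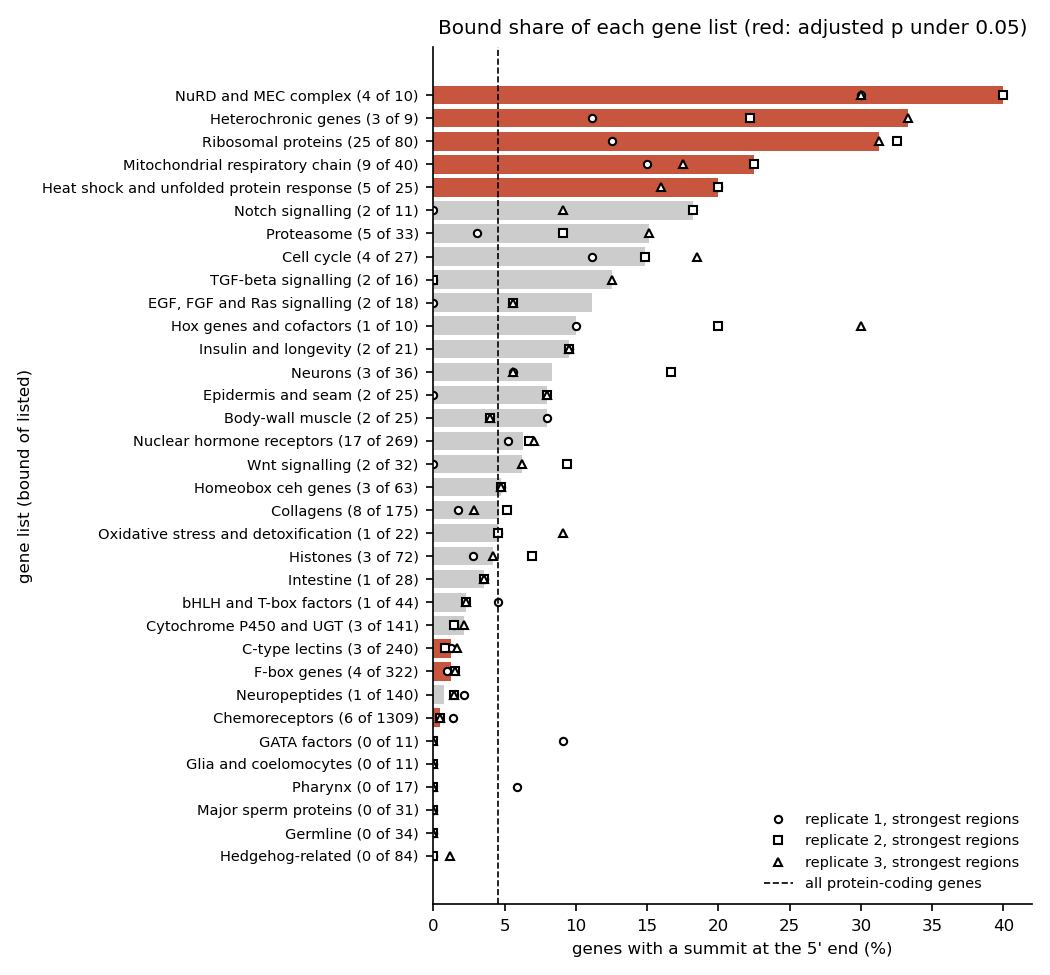
Percent of genes with a summit at the 5' end (x axis) for each gene list (y axis, with bound and listed genes). Bars give the IDR set, red where the adjusted p was under 0.05, points give each replicate's strongest regions, and the dashed line marks the 4.57% of all protein-coding genes.

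Single genes of interest from the biology of EGL-27 were bound in part. The FOXO transcription factor gene daf-16 had 3 IDR peaks in its body and 1000 bp upstream, 1 of them at its 5' end (I, 10749871 to 10750220). A peak with its summit at -136 bp stood upstream of tlp-1, which encodes a zinc finger protein of tail development (IV, 13704043 to 13704392, signal 57.7). The Hox genes mab-5, lin-39 and egl-5, the Wnt genes lin-44 and egl-20, the Frizzled gene lin-17, the GATA factor gene elt-3 and unc-119 had 0 IDR peaks in the gene and 1000 bp upstream.

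The egl-27 gene itself (II, 6835008 to 6847908) was covered by 12 IDR peaks and had none assigned to its 5' end. The strongest lay in an intron (II, 6842640 to 6843010, signal 219). From II, 6820001 to 6850000, a block of 30 kb that takes in egl-27, the start of tbc-6 and the intergenic sequence upstream of egl-27, there were 22 IDR peaks, or 0.733 per kb against 0.0199 per kb in the genome. No other window of that length held more than 10. The tagged EGL-27 comes from a transgene, and reads from it and from the native gene are not separated.

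**Figure D4:**
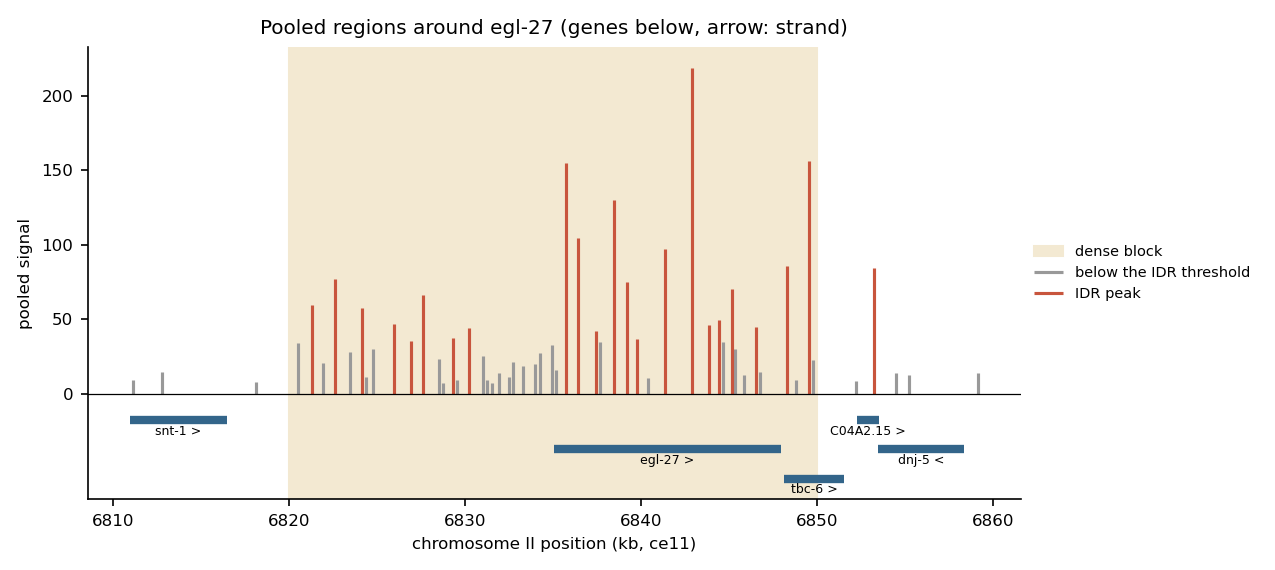
Signal (y axis) of pooled regions at their summits along chromosome II (x axis, kb, ce11), with IDR peaks in red, regions below the IDR threshold in grey, genes as blue bars and the 30 kb block shaded. The block holds 22 IDR peaks and 27 weaker regions.

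The sequence at EGL-27 summits was rich in GA repeats, while the GATA factor site was about as frequent there as in the flanks and its difference from other sequence depended on the control. GAGAGAG occurred within 100 bp of 25.7% of summits against 2.90% of windows centred 500 bp away, a log2 ratio of 3.15 (2.58 ± 0.61 over the replicates, SD, n = 3; exact test, two-sided, adjusted p = 2e-148). WGATAR occurred at 37.9% of summits and in 36.6% of flanks, a log2 ratio of 0.05 (0.04 ± 0.05, SD, n = 3; exact test, two-sided, p = 0.353). The comparison with promoters of unbound genes at the same distance from the 5' end took only the 930 promoter summits. WGATAR was less frequent at these (31.7% against 37.2%, log2 ratio -0.23, Fisher's exact test, p = 0.0147). At all summits it was more frequent than in windows matched on G+C, with a log2 ratio of 0.52 (Fisher's exact test, p = 7.43e-15).

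Of 16 consensus sites 5 were more frequent and 6 less frequent at summits than in flanks. The E-box CACGTG (9.11% against 3.48%, log2 ratio 1.39), the Sp1 GC box (8.96% against 3.81%, log2 ratio 1.24), the DAF-16-associated element TGATAAG, which contains a GATA core (7.16% against 3.25%, log2 ratio 1.14), and the nuclear receptor site AGGTCA (log2 ratio 0.61) were the other higher sites. Lower ones were the homeodomain site TAATTA (log2 ratio -1.21), tracts of T (-1.13), the heat shock element (-0.997), the TCF/LEF site (-0.89), the PBX-Hox site (-0.35) and the FOXO site (-0.35). On the peaks shared by both others without replicates 1, 2 and 3, the exact test gave an adjusted p of 0.0759, 0.311 and 0.578 for the FOXO site and of 0.0747, 0.735 and 0.737 for the nuclear receptor site. The log2 ratios there were -0.40, -0.37 and -0.24 for the FOXO site and 0.39, 0.14 and 0.13 for the nuclear receptor site. The TGATAAG call was lost by that exact test without replicate 2 (adjusted p = 0.143) or replicate 3 (adjusted p = 0.156), among peaks found in every replicate (adjusted p = 0.110) and against promoters of unbound genes (log2 ratio 0.56, adjusted p = 0.0967). All comparisons with unbound promoters took promoter summits only. Among peaks found in every replicate and against unbound promoters, the exact tests gave an adjusted p of 0.328 and 0.0967 for the FOXO site, with log2 ratios of -0.37 and -0.49, and of 0.959 and 0.524 for the nuclear receptor site. The SKN-1 site RTCAT (51.9% against 54.2%, exact test, adjusted p = 0.137) passed as less frequent without replicate 1 (adjusted p = 0.0406), replicate 2 (adjusted p = 0.00799) or replicate 3 (adjusted p = 0.0286), in windows of 50 bp (adjusted p = 0.00885), in the 998 peaks of highest signal (adjusted p = 0.00156), among peaks found in every replicate (adjusted p = 0.0119) and against unbound promoters (adjusted p = 1.18e-04). The T-box site passed as less frequent without replicate 3 (log2 ratio -1.38, exact test, adjusted p = 0.00966) and among peaks found in every replicate (log2 ratio -1.44, adjusted p = 0.0173), and not with all peaks (adjusted p = 0.397). In a search over 2080 hexamers, 779 were more frequent and 606 less frequent at summits. The largest ratios were for GCGCGC (10.1% against 1.43%, log2 ratio 2.82), CGCGCG (log2 ratio 2.74), ACGCAG (26.2% against 3.93%, log2 ratio 2.74), GACGCA (log2 ratio 2.62) and AGACGC (log2 ratio 2.53). Mean G+C content was 44.3% at summits and 35.7% in flanks. Against windows matched on G+C, 4 of the 6 lower sites ended as calls by Fisher's exact test: TAATTA (log2 ratio 0.05, adjusted p = 0.924), tracts of T (0.16, adjusted p = 0.339), TCF/LEF (-0.34, adjusted p = 0.0633) and PBX-Hox (-0.19, adjusted p = 0.168). The FOXO site turned to more frequent (0.72, exact test, adjusted p = 0.00299), the heat shock element stayed lower (-0.75), and the 5 higher sites stayed higher, with log2 ratios of 0.89 for CACGTG, 0.53 for the GC box, 1.49 for TGATAAG, 0.59 for AGGTCA and 3.31 for GAGAGAG. For CACGTG and AGGTCA the highest of 20 versions with permuted letters had larger summit-to-flank log2 ratios (1.56 and 0.98) than the site itself. The GC box had too few permuted versions (5) for a value.

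**Figure D5:**
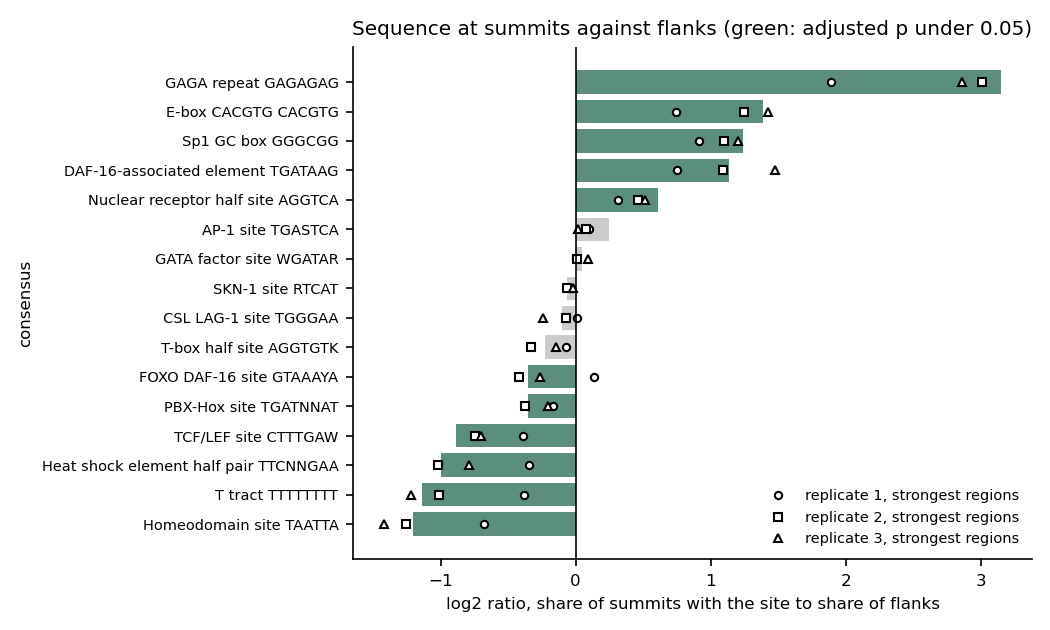
Log2 ratio of the share of summits with a site to the share of flanks (x axis) for 16 consensus sites (y axis). Bars give the IDR set, green where the adjusted p was under 0.05, and points each replicate's strongest regions, with GAGAGAG at 3.15 and WGATAR at 0.05.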

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

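The test of the sequence upstream of egl-27 and both tests of replicate 1 were chosen only after the results they measure had been seen.

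The 30 kb block around egl-27 held 27 regions of the pooled list below the IDR threshold, outside the set used for the comparisons, where the mean of the genome would give 8.38, and replicates 1, 2 and 3 had 29, 46 and 45 regions there against 3.96, 8.98 and 8.98. Binding of EGL-27 within the body of its own gene alone would leave the upstream sequence ordinary, but the 10 kb upstream held 18 regions, more than 99.99% of 10 kb windows. Binding to sequence upstream of the gene would raise that number as well, so the test cannot decide on binding at the locus as a whole. Extra copies of egl-27 from the transgene, if it was built from a fosmid with its flanking sequence, may account for the block: egl-27 with 10 kb on each side held 1.37 regions per kb, above 100% of 2054 genes of similar length (median 0.299). The unc-119 gene stood at 0.228 per kb, the 33.0th percentile, and the labels do not say which copy of that marker the transgene carries. The authors made these lists with a control, and whether that control carries the transgene was not examined. Real binding at this locus was not separated from copy number, because the control itself was not used here.

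Replicate 1 shared fewer regions with the IDR set than the others. A failed precipitation would share few strong peaks, but 99% of the 100 strongest IDR peaks were in its list. Those peaks were ranked by pooled signal that includes replicate 1, and any overlap with its whole list counted. The test therefore cannot exclude a poor precipitation that still recovered the strongest sites. Lower depth or enrichment may account for the difference. The whole list of replicate 1 held 38.4 percentage points more of the strongest than of the weakest bin of IDR peaks. These bins were made by pooled signal as well. When the same number of strongest regions was taken from each replicate, every replicate held less of the weakest bin than of the strongest. The shares were 15% and 63.9% in replicate 1, 48.2% and 99.8% in replicate 2, and 48.2% and 100% in replicate 3. The test therefore cannot single out depth or enrichment in replicate 1. Depth and enrichment were not separated, because no read counts were used here, a library of another target with many sites in common was not tested, and no biological explanation was tested because all replicates form 1 group.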

How the results depend on the processing

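The transcript 5' ends, the G+C-matched control and the removal of the egl-27 block were chosen after seeing the data. The promoter excess, the X excess and the positive rank agreement kept their direction and passed their tests under every alternative run. Promoter shares were 37.9% to 57.2%, X ratios 1.34 to 1.82 and rho 0.371 to 0.511. With a replicate left out, rho was that of the 1 remaining pair over the same IDR peaks as above, so it is no separate check. By construction the stronger IDR peaks numbered 998. Peaks found in every replicate numbered 283 with 50% reciprocal overlap, 753 with the 2N strongest regions, and 544 to 1246 with 1 replicate left out, the highest without replicate 1. Bound genes numbered 486 with the stronger peaks, 234 with peaks found in every replicate and 254 to 576 with 1 replicate left out, which keeps only peaks found in both others. Lists past the threshold numbered 5, 3 and 3 to 6 in these settings, for which fewer bound genes were tested, and rose from 8 to 9 with transcript 5' ends, 10 with every gene in the window, and 11 with 2000 bp promoters or the distance covariate. The log2 ratio of the GATA site turned to -0.23 at promoter summits against unbound promoters. It rose to 0.52, past the threshold, at all summits against G+C-matched windows. There the homeodomain (0.0468), T tract (0.16) and FOXO (0.72) sites changed sign, and the cause was not tested. Against permuted letters 2 sites passed, GAGAGAG and TGATAAG (at most 20 versions, p not adjusted), and CACGTG and AGGTCA did not. The PBX-Hox (0.52) and FOXO (0.40) sites changed sign without passing, cause not tested. The homeodomain, Sp1 and T tract sites had too few permuted versions (13, 5 and 0) for a value. Of 195 alternative values for lists and sites that had passed with all peaks, 143 kept direction and side of the threshold, 47 lost the threshold and 5 changed sign. Of those that had not passed, the proteasome, neuropeptides, Hedgehog-related, cell cycle and EGF, FGF and Ras lists and the GATA, SKN-1 and T-box sites did so in some settings. No paired analysis was possible because there is 1 group. Depth is unknown, so it is not known which weak peaks more reads would have kept.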

Other observations

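The tests of tRNA and snoRNA genes and of the signal at ribosomal protein genes were chosen only after the results they measure had been seen.

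Genes of tRNAs, snoRNAs and snRNAs had more EGL-27 summits nearby than random positions, while miRNA and piRNA genes did not. Summits lay within 100 bp of a tRNA gene for 4.51% of IDR peaks (90 peaks, 100 of 612 tRNA genes), against 0.180% at random and at most 0.801% in any of 100000 draws. For snoRNA genes the share was 3.15% (63 peaks, 63 of 346 genes) against 0.115%, and for snRNA genes 1.202% (24 peaks) against 0.0372%, each with an adjusted p of 1.5e-05 in 100000 binomial draws. The replicates gave 3.10% ± 1.29 for tRNA genes and 2.19% ± 1.12 for snoRNA genes (SD, n = 3). Only 1 summit was near a miRNA gene (0.0501% against 0.0754%), piRNA genes had fewer than random (0.501% against 1.95%) and lincRNA genes more (0.601% against 0.279%, 100000 binomial draws, adjusted p = 0.0148). No immunoprecipitation of an unrelated protein was used here, so a general pull-down of highly transcribed genes was not tested.

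Ribosomal protein genes were bound more often, and the peaks there were also stronger. Their median signal was 73.9 against 52.3 at other bound genes, a difference of 21.6 (permutation test, two-sided, p = 0.00663).

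On X, some of the strongest peaks lay outside promoters, and a hypothesis was that these may be recruitment sites of the dosage compensation complex, which carry the MEX sequence TCGCGCAGGGAG. With at most 2 mismatches the sequence was found at 15 of 271 non-promoter X peaks (5.54%) and 7 of 796 autosomal ones (0.879%), a ratio of 6.29 (Fisher's exact test, two-sided, p = 2.45e-05), and in 0.426% of flanks. Of the 50 strongest IDR peaks 13 were non-promoter peaks on X, and 8 of these had the sequence, against 0 of 16 on autosomes. The region at X, 11093938 to 11094380 matched it with 0 mismatches. At promoter peaks the sequence was found in 2.84% on X and 1.19% on autosomes. The flanks were not split by chromosome, so how often X sequence in general holds it was not measured. Positions of dosage compensation complex binding were not used here, so occupancy by that complex remains untested.

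GA repeats and CG-containing hexamers marked summits, which also had a higher G+C content than flanks. G+C content alone would leave little difference from windows matched on it (44.1% against 44.3%), but the ratio of the GAGAGAG share at summits to that in such windows was 9.88, and the 5 hexamers had log2 ratios of 1.84 (GCGCGC) to 2.22 (GACGCA). Base composition without order would give permuted versions the same ratio, but the log2 ratio of GAGAGAG exceeded the highest of 20 permuted versions by 0.72. These versions were themselves more frequent at summits than in flanks (mean log2 ratio 1.43, from 0.42 to 2.43). Composition without order was therefore not excluded as a part of the ratio. The matched windows were not matched on distance to genes. At promoter summits GAGAGAG occurred in 19.9%, against 3.33% of unbound promoters at the same distance from the 5' end (log2 ratio 2.58). The share over all summits was higher (25.7%), so the repeat was not limited to promoters, and open promoters alone would not account for it. A sequence shared by open promoters of many factors may still be a source at promoter summits, since no other factor was used here.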
